A study of Homo sapiens with 12 samples.

How the data were processed

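RNA was extracted from RBE cells with TRIzol and made into libraries with the NEBNext Ultra RNA kit, per the labels' protocols. The submitters' processing notes name STAR, HTSeq 0.6.0, DESeq2 and the hg38 genome build, without saying what each was used for. The gene annotation and the strand setting of the counting are not given in the sources used here, so antisense partners and overlapping genes cannot be told apart. The authors deposited 1 table of raw counts per gene, 19932 gene symbols by 12 columns, in whole numbers, with no normalization. No row lacked a gene name, and 3622 genes had no count in any library.

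Each column was assigned to a sample from its name alone. The names use short codes that the labels do not explain. They were read as knockdown, overexpression and the vector control of each, with the replicate number. This reading could not be checked against a label, and every group statement rests on it. The 3 replicates of a group were compared before use, and all pairs differed by more than sampling noise, with a chi-square per degree of freedom of 3.965 to 16.09.

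Total counts were 13192525 to 15286370 per library. The main test was the quasi-likelihood test of edgeR 4.0.16 (robust fit, two-sided) in R 4.3.3, on the counts as deposited. All 12 libraries entered 1 fit with group as the factor, TMM scaling and the filterByExpr low-count filter. That filter kept 12412 genes, which hold 99.957% of counts. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The comparisons were sgSLC12A5 against sgNC, LvSLC12A5 against LvNC, the difference of these effects, and LvNC against sgNC. The CPM values printed and drawn per group are counts over the library's total count, without TMM scaling. The log2 CPM used for the components, the correlations and camera are TMM-scaled, and fold changes are those of the fit. Standard errors are the absolute log2 fold change divided by the square root of the F statistic.

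Before the data were examined, 36 gene lists, the tests, the alternatives and the rule for named genes were fixed. Of 776 list entries, 775 were found in the table, older symbols included. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. An estimated correlation and fry were the alternatives. Named genes were SLC12A5 and the 10 genes higher and 10 lower by the largest fold change in each main comparison. These had to have an adjusted p under 0.05, a mean CPM of at least 2 and groups that did not overlap. Up to 4 members per list, 10 genes per pattern of opposite or same direction, and 5 genes each way between the controls were named too.

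Gene positions and identifiers came from GENCODE release 29 on hg38, in which all 19932 symbols were found, 19907 as protein-coding genes. Transcript length and GC content were known for 99.85% of the tested genes.

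The steps were tested on simulated counts with known changes. For the knockdown comparison (12312 genes), 18.8% of genes changed 1.25-fold were recovered, 64% at 1.5-fold, 87.8% at 2-fold and 95.9% at 4-fold, and 7.55% of calls were false. For the overexpression comparison (12314 genes), the shares were 16.3%, 63.3%, 96% and 98%, and 4.43% of calls were false. The simulations called 159 and 158 genes, far fewer than the real comparisons, so these shares need not hold there.

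The alternatives were DESeq2 size factors, library size only, the DESeq2 1.42.0 Wald test, limma-voom, no count filter, a filter of CPM 1 in 6 libraries, a fit on only the 2 groups compared, the replicate number as a block, a minimum of 2-fold, and each replicate left out. For lists, a prior count of 0.5 was tried too. Setting each manipulated group against the control of the other arm was added after seeing the data. Figures were drawn with matplotlib.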

Results

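Gene expression was measured by RNA sequencing in RBE, an established human intrahepatic cholangiocarcinoma (bile duct cancer) cell line. The series holds 12 libraries in 4 groups of 3. One group carried a CRISPR guide against SLC12A5 (sgSLC12A5, labelled a knockdown) and was set against cells with a control guide (sgNC). Another carried a lentivirus for SLC12A5 overexpression (LvSLC12A5) and was set against cells with a control lentivirus (LvNC). SLC12A5 encodes KCC2, a potassium-chloride cotransporter known mainly from neurons. Each library held between 13192525 and 15286370 counts, and 12412 of the 19932 listed genes passed the low-count filter. The columns of the count table were assigned to groups from their names alone, which the labels do not explain. Nothing in the labels says that the 3 samples of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

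The 4 groups separated from each other in a principal component analysis. The first component held 31.2% of the variance and set the sgNC libraries, with scores from 27.94 to 36.22, apart from all other libraries, whose scores lay between -26.6 and -1.465. The second component held 20.9% and separated the sgSLC12A5 libraries, at 21.76 to 23.25, from the LvSLC12A5 libraries, at -22.53 to -21.51, with both controls between them. Correlations of TMM-scaled log2 CPM (counts scaled to a common library size) were 0.9858 to 0.99213 within groups and 0.96465 to 0.98663 between groups.

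**Figure D1:**
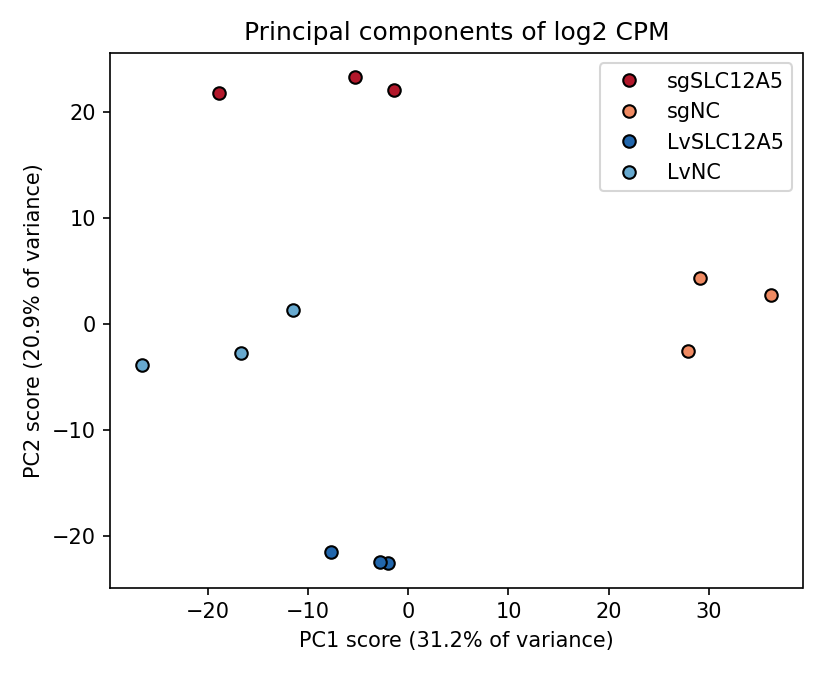
Scores of the 12 libraries on the first (x axis, 31.2% of the variance) and second (y axis, 20.9%) principal components of log2 CPM, 1 point per library, coloured by group. The 3 sgNC libraries lie apart on the first component and the sgSLC12A5 and LvSLC12A5 libraries at opposite ends of the second.

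SLC12A5 itself was read first, since it checks the labels. The gene (ENSG00000124140.13) lies on chromosome 20 from 46021690 to 46060152 on the plus strand of hg38. It was near the detection limit in all groups. The libraries labelled sgSLC12A5 held 33, 21 and 12 counts and the sgNC libraries 7, 11 and 2, or 1.52 ± 0.72 and 0.453 ± 0.316 CPM (SD, n = 3). SLC12A5 was thus higher, not lower, in the libraries labelled knockdown, by 1.72 on the log2 scale (SE 0.553, adjusted p = 0.0253, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The call was lost without sgSLC12A5 replicate 1 (adjusted p = 0.132) or 2 (0.0547) and without sgNC replicate 1 (0.0576) or 3 (0.127). LvSLC12A5 libraries held 4, 8 and 15 counts and LvNC libraries 7, 5 and 1, or 0.631 ± 0.393 and 0.311 ± 0.211 CPM. That difference, a log2 fold change of 0.99 (SE 0.691, adjusted p = 0.401), was not detectable at this depth. By counting error alone, the summed counts of 27 against 13 gave a ratio of 2 in the labelled direction (95% exact Poisson interval 0.998 to 4.23, exact Poisson p = 0.0398), which leaves out the spread between libraries. The transcript counts thus do not bear out the overexpression label. No LvSLC12A5 library exceeded 1.064 CPM. The interval by counting error alone ended at 4.23, but without the spread between libraries it does not bound the size of a rise. Whether transcript from the lentivirus would be counted as SLC12A5 was not tested. The knockdown label goes against the counts. Counts at a CRISPR-edited gene do not measure its protein. Every direction given for the sgSLC12A5 libraries, or as one with overexpression, is a direction for the libraries so labelled.

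**Figure D2:**
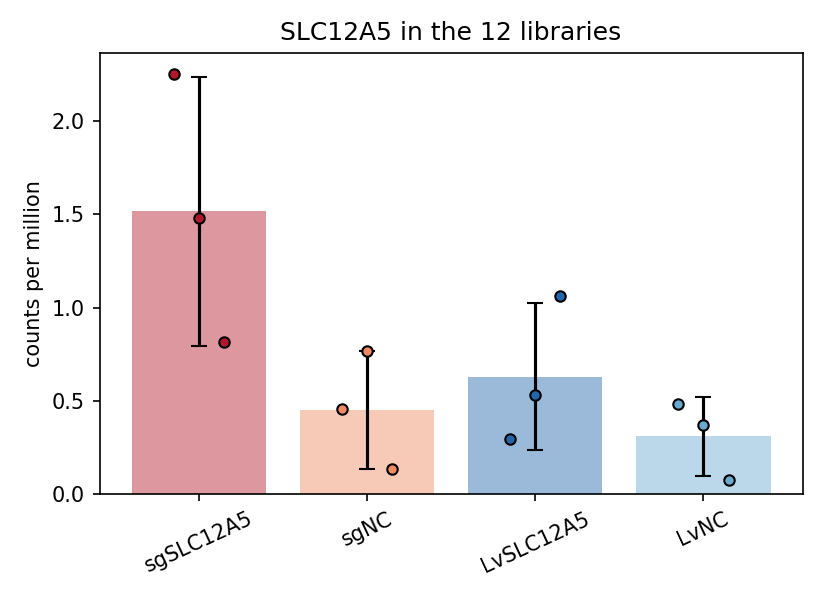
SLC12A5 level in CPM (y axis, from 0) in the 4 groups (x axis); points are the 12 libraries, bars the group means and error bars 1 SD (n = 3). The group labelled sgSLC12A5 has the highest mean, 1.52 CPM, against 0.453 in sgNC, 0.631 in LvSLC12A5 and 0.311 in LvNC.

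The first comparison asked which genes differed between the libraries labelled sgSLC12A5 and the guide control. Among the genes higher in the libraries labelled sgSLC12A5 were CDH1, which encodes the epithelial adhesion protein E-cadherin, and DKK3, a secreted protein of the Dickkopf family. CDH1 (ENSG00000039068.18, chromosome 16, 68737225 to 68835548) stood at 6.95 ± 1.28 against 0.251 ± 0.16 CPM, a log2 fold change of 4.75 (SE 0.434, adjusted p = 1.25e-07). DKK3 (ENSG00000050165.17, chromosome 11, 11963106 to 12009769) stood at 59.7 ± 12.6 against 5.73 ± 0.576 CPM, 10.3-fold higher (adjusted p = 1.86e-13). PALM rose by 4.39 on the log2 scale, RNF182 by 3.57, the retinaldehyde dehydrogenase gene ALDH1A1 by 3.19, WDR72 by 2.70, SCEL by 2.59 and the synaptotagmin gene SYT13 by 2.46. DUSP13, which overlaps SAMD8, rose by 2.53. Against LvNC in place of sgNC, chosen after seeing the data, DKK3 (1.12, adjusted p = 1.14e-05), RNF182 (0.88, 0.0284) and DUSP13 (2.26, 0.00103) were again higher. CDH1 (0.41, adjusted p = 0.37), PALM (0.24, 0.546), ALDH1A1 (-0.07, 0.884), WDR72 (-0.06, 0.897), SCEL (-0.32, 0.37) and SYT13 (0.06, 0.895) were not called, so these differences were not seen against both controls. Set against the LvSLC12A5 libraries, also chosen after seeing the data, CDH1 (1.14, adjusted p = 0.00732), PALM (1.59, 0.000125), ALDH1A1 (1.24, 0.00131) and WDR72 (1.485, 0.000366) were higher. SCEL (0.20, 0.559) and SYT13 (0.24, 0.451) were not called there.

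Among the genes lower in the libraries labelled sgSLC12A5 were MSLN and STC2. MSLN, the gene of the cell-surface glycoprotein mesothelin (chromosome 16, 760762 to 768865), had 54, 49 and 72 counts in sgNC and 0, 5 and 0 in the libraries labelled sgSLC12A5. That call (adjusted p = 1.2e-05) was lost with DESeq2 (adjusted p = 0.199). STC2, which encodes the secreted glycoprotein stanniocalcin 2, was 8.23-fold lower at 6.38 ± 0.303 against 52.1 ± 14.4 CPM (adjusted p = 9.77e-10). The collagen gene COL21A1 fell by 3.34 on the log2 scale, the tight junction gene CLDN3 by 2.85, the activin subunit gene INHBA by 2.56, the transcription factor gene FOXP2 by 2.47, the GDNF receptor gene GFRA1 by 2.39, MGAT5B by 2.36 and CCBE1 by 2.29. ADGRV1, which overlaps LYSMD3, had a log2 fold change of -2.82. Against LvNC, STC2 (-1.74, adjusted p = 1.24e-05), CLDN3 (-2.36, 6.06e-05), GFRA1 (-2.80, 3.28e-06), MGAT5B (-1.65, 7.03e-05) and CCBE1 (-0.97, 0.00724) were again lower. INHBA (-0.89, adjusted p = 0.125), FOXP2 (-0.22, 0.714) and ADGRV1 (-0.48, 0.326) were not called, nor were COL21A1 (0.64, 0.522) and MSLN (3.83, 0.212), which pointed the other way.

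Of the 35 gene lists with at least 5 tested members, 6 differed as a group with camera at the preset correlation, and none of the 6 did with an estimated correlation. Among 10 splits of the 6 libraries, 5 called at least 6 lists, so this number does not set the real grouping apart. NRF2 targets rose: 9 of 22 members were higher and 0 lower (11 and 0 adjusted over the list alone; list adjusted p = 0.00182), and adjusted p = 0.617 with an estimated correlation. They included the glutathione synthesis gene GCLM (log2 0.52, SE 0.0909), the quinone reductase gene NQO1 (0.52, SE 0.0964) and the organic anion exporter gene ABCC2 (0.55, SE 0.122). Interferon-stimulated genes were higher in 8 of 17 cases and lower in 0 (8 and 0 adjusted over the list alone; adjusted p = 0.0104, and adjusted p = 0.617 with an estimated correlation), among them IFIT2 (1.06, SE 0.192), OAS1 (1.05, SE 0.254), SAMD9 (0.99, SE 0.228) and DDX60 (0.85, SE 0.206).

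Immediate early genes fell: 10 of 17 were lower and 1 higher (10 and 1 adjusted over the list alone; adjusted p = 0.00428, and adjusted p = 0.617 with an estimated correlation), including ATF3 (-1.74, SE 0.22), KLF4 (-0.83, SE 0.146), MYC (-0.69, SE 0.102) and IER2 (-0.47, SE 0.105). Of the ATF4 and amino acid response genes, 9 of 19 were lower and 2 higher (11 and 2 adjusted over the list alone; adjusted p = 0.00828, and adjusted p = 0.617 with an estimated correlation). STC2, ATF3, CEBPB (-0.62, SE 0.11) and the glutamine transporter gene SLC1A5 (-0.45, SE 0.0848) were among them. The NF-kB and inflammation list had 10 of 21 members lower and 3 higher (11 and 3 adjusted over the list alone; adjusted p = 0.0104, and adjusted p = 0.617 with an estimated correlation), including NFKB2 (-0.95, SE 0.12), RELB (-1.05, SE 0.158) and CSF2 (-1.48, SE 0.261). Targets of TGF-beta had 8 of 17 members lower and 2 higher (8 and 3 adjusted over the list alone; adjusted p = 0.0492, and adjusted p = 0.617 with an estimated correlation), with the basement membrane gene COL4A1 at -0.71 (SE 0.125). This last call was also lost without sgSLC12A5 replicate 1 (adjusted p = 0.112), sgNC replicate 2 (0.0861) or sgNC replicate 3 (0.0765), with DESeq2 size factors (0.0511), with a prior count of 0.5 (0.0527) and on only the 2 groups compared (0.0667).

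These list results depended on the control. With LvNC in place of sgNC, chosen after seeing the data, NRF2 targets were again higher (camera at the preset correlation, adjusted p = 3.31e-05), and the other 5 list results were lost or turned. ATF4 and amino acid response genes were then higher (adjusted p = 0.048). Interferon-stimulated genes pointed lower (0.191), the NF-kB list (0.82) and immediate early genes (0.19) pointed higher, and TGF-beta targets pointed lower (0.535), none of them called. NFKB2 and SLC1A5 were called with the other sign against LvNC, at 0.70 (SE 0.124) and 0.29 (SE 0.085).

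In all, 3038 genes differed between the libraries labelled sgSLC12A5 and sgNC, 1554 higher and 1484 lower, and 207 and 177 of them by at least 2-fold. The 3 libraries of one group did not overlap those of the other in 37.98% of genes, where chance gives 10%. Against LvNC in place of sgNC, a comparison chosen after seeing the data, 1121 genes differed, of which 332 had the same direction as in the 3038 and 70 the opposite one, against 137.4 and 136.9 for independent lists. The log2 fold changes against the 2 controls correlated at r = 0.286. Simulated unchanged groups that share the sgSLC12A5 libraries gave a mean of 0.497. That simulation holds no gap between the control lines, which differed here in 4118 genes, so it is no measure for the observed value.

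**Figure D3:**
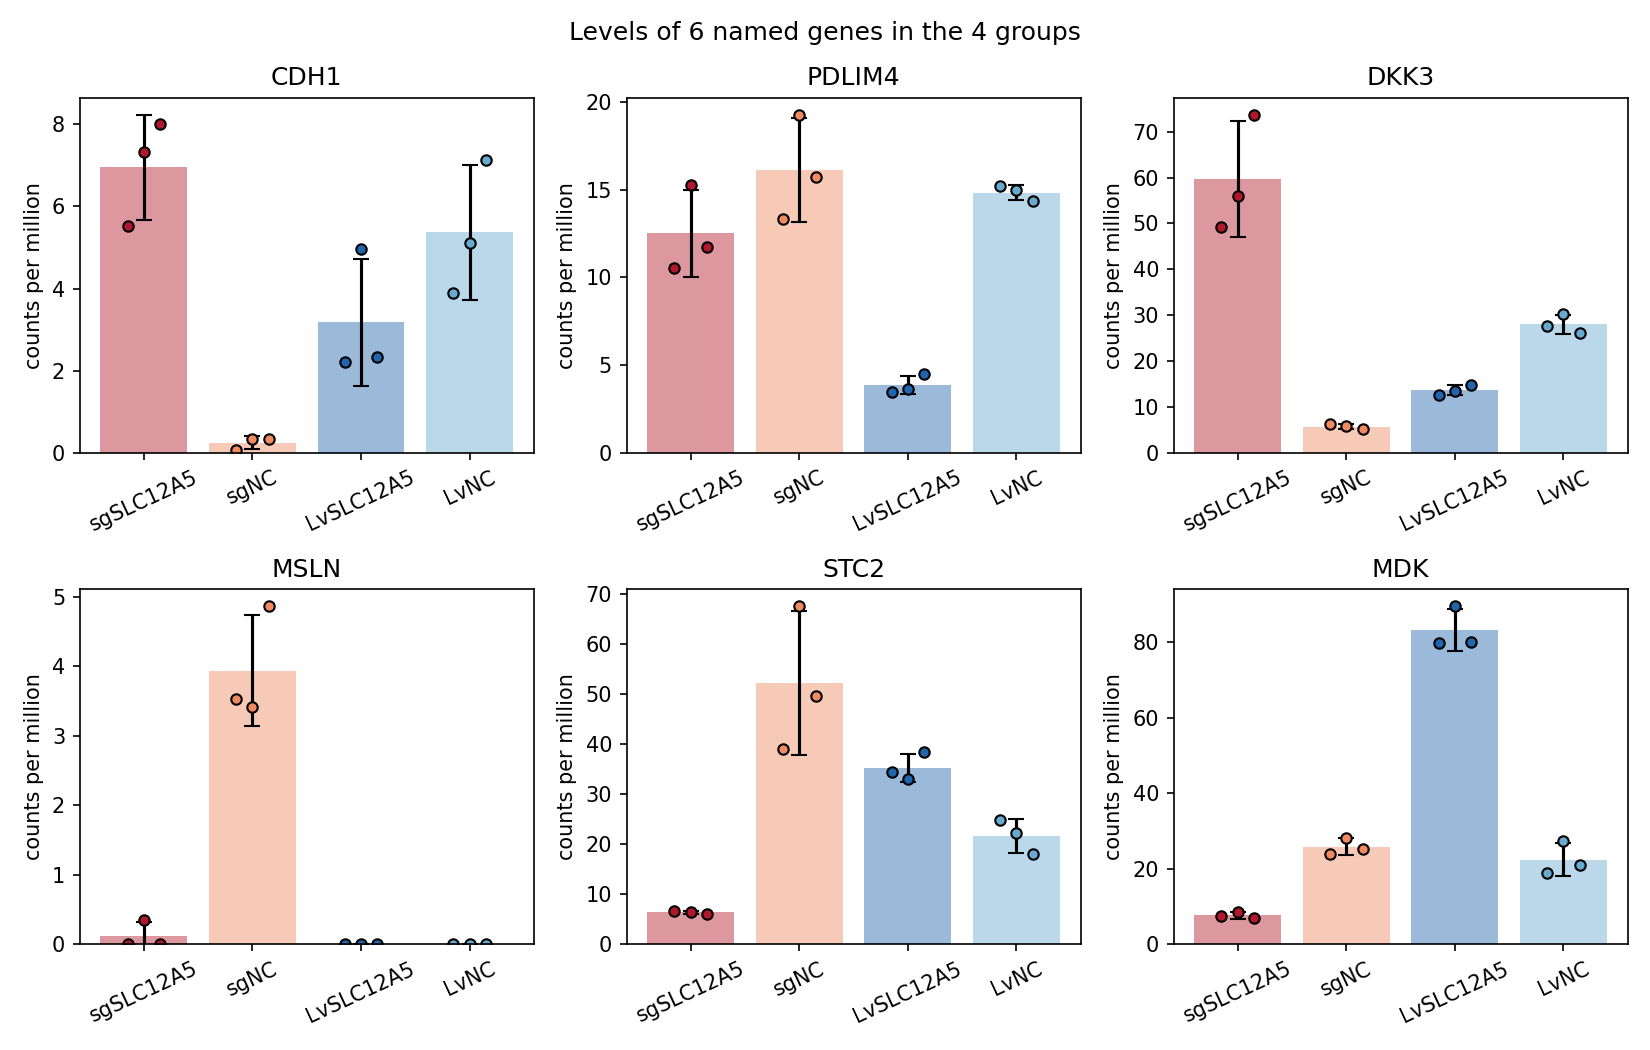
Levels of 6 named genes in CPM (y axes, each from 0) in the 4 groups (x axes); points are libraries, bars group means and error bars 1 SD (n = 3). CDH1 is at 0.251 CPM in sgNC and 3.18 to 6.95 in the other groups, MSLN is at 3.94 CPM in sgNC and at most 0.117 elsewhere, and MDK is highest in LvSLC12A5, at 83.2 CPM.

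The second comparison asked which genes differed between the overexpression libraries and the lentiviral control. MDK, the gene of the growth factor midkine (ENSG00000110492.15, chromosome 11, 46380756 to 46383837), was 3.73-fold higher at 83.2 ± 5.52 against 22.4 ± 4.45 CPM (log2 1.90, SE 0.127, adjusted p = 1.7e-09). MID1IP1, whose product takes part in lipid synthesis, was 4.46-fold higher (adjusted p = 4.97e-09). HHIP, which encodes a hedgehog-binding protein, rose by 2.45 on the log2 scale, the granzyme B inhibitor gene SERPINB9 by 2.47, the transcription factor gene CREB3L1 by 2.01, the retinoic acid hydroxylase gene CYP26B1 by 1.83, STEAP1 by 1.63 and the inflammasome adaptor gene PYCARD by 1.54. DYNLT3 and PRRG1, which share an overlapping annotated locus, rose by 2.60 and 1.76. Against sgNC in place of LvNC, chosen after seeing the data, MDK (1.66, adjusted p = 5.48e-09), SERPINB9 (1.46, 0.00279), CREB3L1 (0.87, 0.00426), STEAP1 (0.73, 0.045), PYCARD (1.12, 1.12e-05), DYNLT3 (3.76, 2.77e-06) and PRRG1 (3.33, 4.7e-07) were again higher. MID1IP1 (-0.03, adjusted p = 0.907), HHIP (0.63, 0.112) and CYP26B1 (0.62, 0.0845) were not called.

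Genes lower with overexpression included PDLIM4, at 3.87 ± 0.528 against 14.8 ± 0.448 CPM (log2 -1.93, SE 0.185), and the renal and intestinal scaffold gene PDZK1 (-1.89, SE 0.326). GGT5 was at -2.44 (SE 0.421), SYT11 at -2.17 (SE 0.402), SLC22A31 at -1.71 (SE 0.282), RNF182 at -1.70 (SE 0.3) and OLFM4 at -1.60 (SE 0.305). KRT86 (-2.45), GSTM1 (-1.75) and HLA-DRB1 (-1.78) also fell, but share sequence with near-identical family members and are uncertain. Against sgNC, PDLIM4 (-2.09, adjusted p = 7.05e-08), GGT5 (-2.30, 0.000477), KRT86 (-1.65, 0.0113) and GSTM1 (-2.35, 1.9e-06) were again lower. PDZK1 (0.10, adjusted p = 0.891), SYT11 (0.11, 0.898), SLC22A31 (-0.78, 0.0572) and RNF182 (0.99, 0.0685) were not called, and HLA-DRB1 (2.16, 0.0047) and OLFM4 (1.86, 0.00239) were called higher.

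Camera called 9 lists in this comparison at the preset correlation and 0 with an estimated correlation. The respiratory chain genes encoded in the nucleus fell, with 6 of 36 members lower and 1 higher (7 and 2 adjusted over the list alone; adjusted p = 0.00667, and adjusted p = 0.636 with an estimated correlation), among them COX4I1 (-0.66, SE 0.0857) and SDHC (-0.49, SE 0.082). Replication histones had 4 of 9 members lower and 0 higher (5 and 0 adjusted over the list alone; adjusted p = 0.00813, and adjusted p = 0.622 with an estimated correlation), with HIST1H2AC at -1.03 (SE 0.217). Histone transcripts are near-identical to each other and mostly lack a poly(A) tail, so their counts are uncertain. Ribosomal protein genes had 4 of 51 lower and 1 higher (4 and 1 adjusted over the list alone; adjusted p = 0.0093, and adjusted p = 0.66 with an estimated correlation), and genes of mitochondrial DNA 1 of 13 lower and 0 higher (1 and 0 adjusted over the list alone; adjusted p = 0.018, and adjusted p = 0.66 with an estimated correlation). Their medians were small, at -0.10 and -0.20 on the log2 scale. The share of counts from mitochondrial DNA was 5.05% to 5.74% in LvSLC12A5 libraries and 5.67% to 6.93% in LvNC libraries.

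NRF2 targets had 4 of 22 members lower and 0 higher (4 and 0 adjusted over the list alone; adjusted p = 0.0224, and adjusted p = 0.636 with an estimated correlation), with ABCC2 2.86-fold lower (-1.52, SE 0.14). Interferon-stimulated genes had 2 of 17 lower and 0 higher (3 and 0 adjusted over the list alone; adjusted p = 0.0093, and adjusted p = 0.636 with an estimated correlation), IFIT3 at -0.82 (SE 0.211) and IFIT1 at -0.88 (SE 0.243). The IFIT3 call was lost without LvSLC12A5 replicate 1 (adjusted p = 0.0746), LvNC replicate 1 (0.06) or LvNC replicate 3 (0.0927), and the IFIT1 call without LvSLC12A5 replicate 1 (0.125) or 3 (0.133) or LvNC replicate 3 (0.155). Antigen presentation genes had 3 of 9 lower and 0 higher (3 and 0 adjusted over the list alone; adjusted p = 0.0232, and adjusted p = 0.433 with an estimated correlation), among them HLA-DRB1 and B2M (-0.56, SE 0.0972). The p53 targets rose, with 5 of 24 higher and 1 lower (6 and 2 adjusted over the list alone). Camera gave them an adjusted p = 0.018, and adjusted p = 0.636 with an estimated correlation. Those higher included the receptor gene EDA2R (1.13, SE 0.18) and the DNA repair gene DDB2 (0.44, SE 0.0979). Chloride channel genes had 1 of 13 higher and 0 lower (1 and 0 adjusted over the list alone; adjusted p = 0.0356, and adjusted p = 0.433 with an estimated correlation).

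All 9 list calls of the overexpression comparison were lost without LvNC replicate 2: the adjusted p was then 0.0745 for the respiratory chain, 0.0706 for histones, 0.139 for ribosomal proteins, 0.0966 for mitochondrial DNA and for NRF2 targets, 0.0699 for interferon-stimulated genes, 0.113 for antigen presentation and for chloride channels, and 0.0745 for p53 targets. NRF2 targets and ribosomal proteins were also lost without LvNC replicate 1 (0.0541 each), and mitochondrial DNA without LvSLC12A5 replicate 1 (0.0927) or LvNC replicate 3 (0.0865). Chloride channels were also lost without LvSLC12A5 replicate 2 (0.0601) or 3 (0.0998) or LvNC replicate 1 (0.102), with no count filter (0.197) and on only the 2 groups compared (0.0506). With sgNC in place of LvNC, chosen after seeing the data, the respiratory chain (9.96e-06) and ribosomal proteins (5.15e-07) were again lower with camera at the preset correlation. The other 7 were not called: histones (0.736), mitochondrial DNA (0.507) and NRF2 targets (0.131) pointed lower and chloride channels higher (0.0571), as against LvNC. The p53 targets then pointed lower (0.636), and interferon-stimulated genes (0.138) and antigen presentation (0.332) higher.

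In all, 1241 genes differed between LvSLC12A5 and LvNC, 614 higher and 627 lower, and 63 and 74 of them by at least 2-fold. The groups did not overlap in 30.62% of genes, where chance gives 10%. The count fell to 552, 679 or 536 without LvSLC12A5 replicate 1, 2 or 3, to 594 without LvNC replicate 1 and to 720 without LvNC replicate 3. Against sgNC in place of LvNC, again chosen after seeing the data, 2922 genes differed, of which 340 had the same direction as in the 1241 and 94 the opposite one, against 146.1 and 146 for independent lists. The log2 fold changes against the 2 controls correlated at r = 0.264. The simulation of unchanged groups that share a manipulated group was run only for the guide arm, where it gave 0.497. It holds no gap between the control lines, so it is no measure for this value either.

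**Figure D4:**
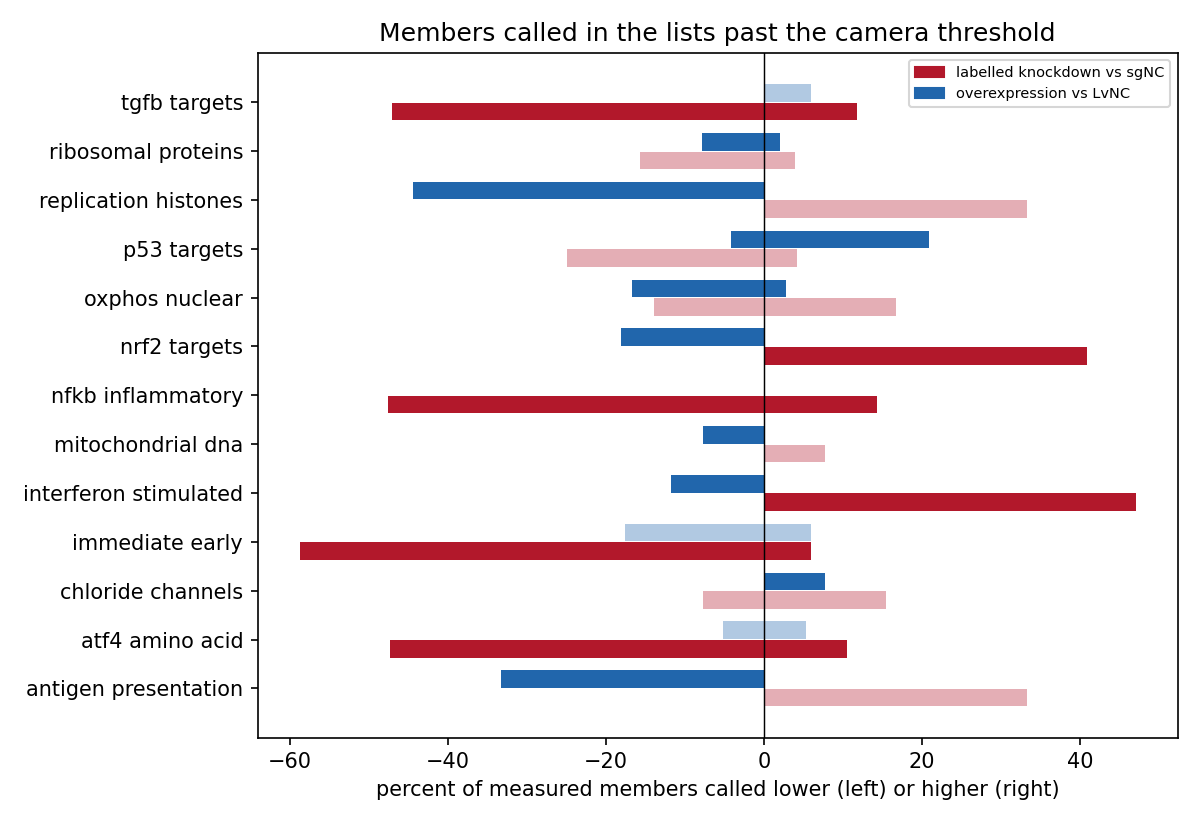
Percent of each list's tested members called lower (left of 0) or higher (right of 0) on the x axis, for the lists (y axis) that passed camera in at least 1 of the comparisons; red bars are the libraries labelled knockdown against sgNC, blue bars overexpression against LvNC, and pale bars lists that did not pass in that comparison. NRF2 targets and interferon-stimulated genes point right in red and left in blue.

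The series has no stated comparison between its arms, but the design lets the 2 manipulations be set side by side without any shared library. More genes moved in opposite directions than in the same direction. In 282 genes the libraries labelled sgSLC12A5 were higher and the overexpression libraries lower, against 78.5 for independent lists (Fisher's exact test, two-sided, p = 1.6e-96, adjusted 6.4e-96 over 4 patterns). In 211 genes the reverse held, against 73.41 (Fisher's exact test, p = 8.42e-51, adjusted 1.68e-50). Genes higher in both numbered 23 against 76.87 (Fisher's exact test, p = 2.45e-14, adjusted 3.27e-14) and genes lower in both 26 against 74.97 (p = 4.88e-12, adjusted 4.88e-12). Genes are not independent replicates, so these p-values describe the overlap only. Across genes the 2 sets of log2 fold changes had a Pearson r of -0.309 and a Spearman rho of -0.365. With no count filter the Pearson r was -0.0921.

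Genes higher in the libraries labelled sgSLC12A5 and lower with overexpression included RNF182 (3.57 and -1.70), OLFM4 (1.90 and -1.60), WDR72 (2.70 and -1.55), PALM (4.39 and -1.35), ALDH1A1 (3.19 and -1.31), MLLT11 (1.65 and -1.20), the cadherin gene CDH16 (1.16 and -1.31) and DKK3 (3.37 and -1.03). Those lower in the first and higher in the second included MID1IP1 (-1.79 and 2.16), MDK (-1.77 and 1.90), MGAT5B (-2.36 and 1.39), IGF2 (-1.36 and 1.45; it overlaps INS-IGF2), GRIN3B (-1.79 and 1.33), SMOC1 (-1.76 and 1.29), HS3ST3A1 (-1.69 and 1.15) and the tetraspanin gene CD82 (-1.20 and 1.03). Against the control of the other arm, chosen after seeing the data, several of these were called with the other sign: OLFM4 (-1.56 and 1.86) and IGF2 (0.96 and -0.86) in both arms, and with overexpression PALM (2.80), ALDH1A1 (1.95), DKK3 (1.22) and WDR72 (1.21). Of the 16 genes named here, MDK (-1.53 and 1.66) and MGAT5B (-1.65 and 0.68) were called in both arms with the signs they had against their own controls. The knockdown directions again belong to libraries whose SLC12A5 counts go against their label.

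Genes that fell in both included the acute-phase gene SAA1 (-1.18 and -1.38) and the fibrinogen gene FGB (-1.44 and -1.04). GGT5 (-1.59 and -2.44) and GFRA1 (-2.39 and -1.47) fell in both too. Higher in both were AMOTL1 (0.91 and 1.05) and the membrane metalloproteinase gene MMP14 (1.03 and 0.45). Against the control of the other arm FGB, GGT5, GFRA1 and MMP14 were called with the same signs in both arms, while SAA1 (-0.61, adjusted p = 0.19) and AMOTL1 (-0.09, 0.663) were not called in the libraries labelled sgSLC12A5. The genes named for these patterns are examples. The opposite calls fell from 493 to 219, 288 or 209 without LvSLC12A5 replicate 1, 2 or 3, to 240 without LvNC replicate 1 and to 305 without LvNC replicate 3. The same-direction calls moved from 49 to 76 without sgSLC12A5 replicate 3, to 24, 32 or 22 without LvSLC12A5 replicate 1, 2 or 3, and to 25 without LvNC replicate 1.

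**Figure D5:**
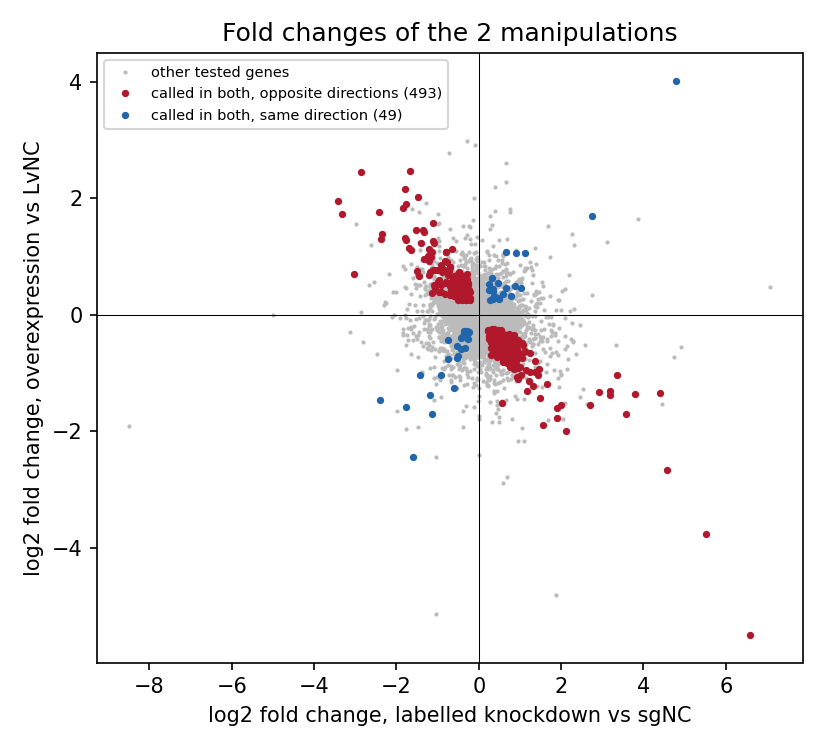
Log2 fold change of the libraries labelled knockdown against sgNC (x axis) and of overexpression against LvNC (y axis), 1 point per tested gene; red points were called in both with opposite signs (493), blue points in both with the same sign (49), grey points are all other genes.

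A test of the difference itself, the effect in the guide arm minus that in the lentiviral arm, called 3539 genes, 1813 with a positive and 1726 with a negative difference. This difference contains the gap between the control lines, LvNC minus sgNC, which alone called 4118 genes. The lists that differed with camera were NRF2 targets (8 of 22 positive, 0 negative, 12 and 0 adjusted over the list alone; adjusted p = 0.00129, and adjusted p = 0.562 with an estimated correlation), interferon-stimulated genes (6 of 17 positive, 0 negative, 7 and 0 adjusted over the list alone; adjusted p = 0.0018, and adjusted p = 0.562 with an estimated correlation), histones (5 of 9 positive, 0 negative, 6 and 0 adjusted over the list alone; adjusted p = 0.0209, and adjusted p = 0.562 with an estimated correlation) and mitochondrial DNA (5 of 13 positive, 0 negative, 5 and 0 adjusted over the list alone; adjusted p = 0.0209, and adjusted p = 0.772 with an estimated correlation). Antigen presentation had 4 of 9 positive and 0 negative (4 and 0 adjusted over the list alone; adjusted p = 0.0362, and adjusted p = 0.562 with an estimated correlation). The p53 targets had 2 of 24 positive and 8 negative (2 and 10 adjusted over the list alone; adjusted p = 0.0209, and adjusted p = 0.604 with an estimated correlation), the NF-kB list 2 of 21 positive and 9 negative (2 and 9 adjusted over the list alone; adjusted p = 0.0351, and adjusted p = 0.562 with an estimated correlation) and TGF-beta targets 2 of 17 positive and 8 negative (2 and 8 adjusted over the list alone; adjusted p = 0.0383, and adjusted p = 0.604 with an estimated correlation).

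The control lines were compared with each other to give the background for both arms. LvNC was higher than sgNC for CDH1 by 4.34 on the log2 scale (SE 0.448), for PALM by 4.15, for OLFM4 by 3.46 and for ALDH1A1 by 3.26. LvNC was lower for COL21A1 (-3.97), the reductase gene DHRS2 (-2.82), ADGRV1 (-2.34), IGF2 (-2.31) and the homeobox gene EN2 (-2.28). ATF4 and amino acid response genes were lower in LvNC in 15 of 19 cases and higher in 0 (15 and 0 adjusted over the list alone; adjusted p = 3.51e-05, and adjusted p = 0.476 with an estimated correlation). Immediate early genes were lower in 11 of 17 and higher in 0 (11 and 0 adjusted over the list alone; adjusted p = 0.000415, and adjusted p = 0.476 with an estimated correlation). Interferon-stimulated genes were higher in LvNC in 6 of 17 and lower in 0 (6 and 0 adjusted over the list alone; adjusted p = 0.00145, and adjusted p = 0.476 with an estimated correlation) and the NF-kB list was lower in 8 of 21 and higher in 4 (8 and 4 adjusted over the list alone; adjusted p = 0.0303, and adjusted p = 0.476 with an estimated correlation), the directions seen for both lists in the libraries labelled sgSLC12A5 against the same sgNC libraries. Epithelial junction genes were higher in 10 of 21 and lower in 2 (10 and 2 adjusted over the list alone; adjusted p = 0.0192, and adjusted p = 0.476 with an estimated correlation) and antigen presentation genes higher in 3 of 9 and lower in 0 (3 and 0 adjusted over the list alone; adjusted p = 0.0303, and adjusted p = 0.476 with an estimated correlation). Ribosomal proteins were lower in 13 of 51 and higher in 2 (13 and 2 adjusted over the list alone; adjusted p = 0.0296, and adjusted p = 0.832 with an estimated correlation) and p53 targets lower in 11 of 24 and higher in 2 (11 and 3 adjusted over the list alone; adjusted p = 0.0303, and adjusted p = 0.632 with an estimated correlation). The ATF4 and immediate early lists were likewise lower in the libraries labelled sgSLC12A5 against sgNC. NRF2 targets (camera adjusted p = 0.975) and TGF-beta targets (0.271), called in those libraries, were not called between the controls. In all, 4118 genes differed, 2006 higher and 2112 lower in LvNC, and 244 and 163 of them by at least 2-fold. Scaled by library size only, 2350 were higher and 1818 lower. The groups did not overlap in 43.2% of genes, where chance gives 10%. The 4118 genes are more than in either main comparison. The fold changes between the controls followed GC content (Spearman rho -0.433) and transcript length (0.289). After a correction for both, 3676 genes were called, of which 2585 were among the 4118. In the knockdown and overexpression comparisons rho with GC content was -0.264 and 0.206. Whether this trend came from the cells or the libraries was not tested. The difference between the control lines includes the vector, the handling and any drift between the lines, which the labels do not separate.

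The knockdown comparison and the comparison of controls share the sgNC libraries. Their calls had the same direction in 1981 genes and opposite directions in 24, against 503.7 and 504.3 for independent lists. Their log2 fold changes correlated at r = 0.743 with a covariance of 0.178. Unchanged groups simulated against the same controls gave a mean r of 0.491, a covariance of 0.0181 and 0.05 shared calls. The simulation holds no difference between groups, so almost no gene could be called there. Its shared calls and its r are thus no measure for the observed ones. With 3 control libraries the sgNC group could not be split into groups of at least 2, so part of the overlap may come from the shared libraries.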

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

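The tests of control positions were chosen after the results were seen, while the GC and length test and the counts of splits were fixed beforehand. The effects of the 2 manipulations differed in 3539 genes by a test of the difference itself, and 8 gene lists differed with camera at the preset correlation and 0 with an estimated correlation (adjusted p = 0.562 to 0.772). Both were singled out because the same kind of contrast, manipulated against control, went different ways in the guide and lentiviral arms. Each effect is measured from its own control, so the gap between the control lines, which called 4118 genes, is part of this difference. Of 100 joint splits of both arms, drawn with a fixed seed and including the real one, 1 reached the real 3539 genes. The highest other was 1781, which argues against a grouping of the libraries within the arms by chance. Each arm's real grouping called genes and its other splits called 0, so these splits do not test whether the 2 effects differ. For the correlation the real size, 0.309, was also the largest, but by a small margin, the highest other being 0.2818. The size fell below 0.2818 in some fits with 1 library left out, and the correlation was -0.0921 with no count filter. The splits were not repeated under those settings, so for the correlation this holds for the main settings only. The split that turns 1 arm round, which would give the same size of correlation and exchange opposite with same-direction calls, was not among those drawn. For the 493 opposite and the 49 same-direction calls the highest other split gave 0, but every other split of either arm called 0 genes, so these counts could come out no other way and say nothing about chance.

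The 493 opposite calls would arise from a dose of SLC12A5 only if the knockdown label holds for the protein, for which this series holds no data, but also if the control lines themselves lay apart, since each arm is measured from its own control. The measured transcript was higher by 1.72 in the libraries labelled sgSLC12A5, a call lost without some single libraries. The 0.99 with overexpression was not called. A dose of the transcript would give same-direction calls only if both rises were real. The 49 such calls, against 151.8 for independent lists, therefore do not decide on it. Against GC content and transcript length as the whole cause, a correction for both gave 734 opposite calls, 2.84 times the 258.3 of independent lists, and 112 same-direction calls in place of 49. The gap between the control lines exceeded the gap between the manipulated lines in 58.6% of the 493 genes, and between 46.6% and 70.8% with 1 library left out, the extremes being without LvNC replicate 3 and LvNC replicate 2. Both control means lay between the manipulated means, as a dose in the labelled directions would have it, in 32.5% (22.5% to 42.3%), and both manipulated means between the control means in 43.8% (32.1% to 57.8%). Since these shares do not decide, for these genes a difference between control lines stays open, and so does a dose in the labelled directions, which the SLC12A5 counts do not support.

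For the 3038 genes called in the libraries labelled sgSLC12A5, the sgNC group was the one farther from the mean of the lentiviral groups in 66.9%, and in 64.1% to 73.1% with 1 library left out. The values are consistent with a guide control line that had moved away from the others, which may account for a large part of these calls. The splits of 6 libraries are too few for a share under 0.05. The real count was 3038 and the highest other 0 for the libraries labelled knockdown, 1241 and 0 for overexpression, and 4118 and 0 for the controls, each real count being reached by 1 of 10 splits. For the gene lists, the real split gave 6 lists for the libraries labelled knockdown and the highest other 9, with 5 of 10 splits giving at least 6. That number of lists is thus no larger than other groupings of the same libraries gave. For overexpression it gave 9 and the highest other 5, with 1 of 10 splits reaching 9.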

How the results depend on the processing

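Under the settings fixed before the data were examined, the correlation, the SLC12A5 fold changes and the called lists kept their direction. The balance of higher and lower calls did turn in some. It went from 1554 and 1484 to 1484 and 1518 for the libraries labelled knockdown with the strict filter. For overexpression it went from 614 and 627 to 639 and 612 with DESeq2 size factors, and for the controls from 2006 and 2112 to 2350 and 1818 by library size only. With a minimum of 2-fold, the counts were 384 for the libraries labelled knockdown, 137 for overexpression, 776 for the difference, 407 for the controls, 49 opposite and 9 in the same direction, by construction of the threshold. The correlation was -0.0921 with no count filter, -0.371 with the strict filter and -0.370 on only the 2 groups compared. With an estimated correlation 0 lists were called in either arm, and with fry 13 and 5. The cause was not tested for the correlation and the lists. With the control of the other arm, chosen after seeing the data, 1121 genes were called for the libraries labelled knockdown and 2922 for overexpression, with a correlation of -0.281. Directions did turn under that setting. Of 179 named genes called for the libraries labelled knockdown 52 were called against LvNC, 9 of them with the other sign, and of 138 for overexpression 72 were called against sgNC, 15 with the other sign. Of the lists, 1 of 6 and 2 of 9 were shared. The cause was not tested. Replicate numbers were not taken as pairs, since not every same-numbered pair exceeded 0.1 in any comparison, but pairing was not excluded. Deviations of libraries with the same number correlated at 0.142, 0.0122 and 0.109 in the guide arm, against -0.162 to 0.0751 for unlike numbers. In the lentiviral arm the values were 0.0546, -0.00701 and -0.0373, against -0.0606 to 0.0585. Between the controls they were 0.0137, 0.288 and 0.0919, against -0.261 to 0.177. With the replicate block, 3551 and 1689 genes were called, and the same-direction count was 78.

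With 1 replicate of a compared group left out, counts ranged from 2241 to 2954 for the libraries labelled knockdown, 536 to 1428 for overexpression, 2805 to 3820 for the difference and 2861 to 4419 for the controls. With any of the 12 libraries left out, they reached 3276 for the libraries labelled knockdown and 1573 for overexpression. Opposite calls ranged from 209 to 609, same-direction calls from 22 to 76 and the correlation from -0.3153 to -0.2394. Lists ranged from 6 to 8 for the libraries labelled knockdown and from 0 to 8 for overexpression, with 0 without LvNC replicate 2. The SLC12A5 log2 fold change ranged from 1.29 to 2.31 for the libraries labelled knockdown and from 0.40 to 1.46 for overexpression. SLC12A5 had no value under the strict filter, nor for overexpression on only the 2 groups compared. Of 4354 values of single named genes, the control of the other arm not among them, 3988 stayed on their side of the threshold, 365 lost a call, 1 gained one and none reversed, and 201 of 304 calls were lost by no alternative. At this depth the smallest simulated change was seldom recovered in the simulation (18.8% and 16.3%). The simulation called 159 and 158 genes, against 3038 and 1241 in the data. Its adjusted threshold was thus stricter, and its shares need not hold for the data. Small effects can still be missed.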

Other observations

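Among the potassium-chloride and sodium-chloride cotransporter genes and their kinases, 1 of 11 was higher and 2 lower in the libraries labelled sgSLC12A5 (1 and 2 adjusted over the list alone; list adjusted p = 0.967 with camera). The lower ones were SLC12A7 (log2 -0.85, SE 0.144) and SLC12A9 (-0.39, SE 0.0986). None of the 11 was called with overexpression (0 and 0 adjusted over the list alone; list adjusted p = 0.395). Epithelial junction genes went both ways in the libraries labelled sgSLC12A5, 6 of 21 higher and 4 lower (6 and 4 adjusted over the list alone; list adjusted p = 0.255). CDH1 rose while CLDN3 (-2.85, SE 0.301) and the splicing regulator gene ESRP2 (-1.78, SE 0.234) fell. Of 16 mesenchymal genes 4 rose and 4 fell (5 and 5 adjusted over the list alone; list adjusted p = 0.854), with S100A4 at 1.37 (SE 0.121) and SNAI2 at -1.10 (SE 0.192). With overexpression 4 of these 16 rose and 2 fell (4 and 2 adjusted over the list alone, list adjusted p = 0.243). CD44 at 0.43 (SE 0.0733) and AXL at 0.49 (SE 0.0942) were higher and S100A4 (-0.79, SE 0.122) lower. Against sgNC in place of LvNC, chosen after seeing the data, CD44 was again higher (0.36, adjusted p = 0.00113). AXL (-0.12, 0.373) and S100A4 (0.01, 0.961) were not called.

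Fibroblast and matrix genes, of which these cells express 10 tested members, were lower in 4 cases and higher in 1 in the libraries labelled sgSLC12A5 (5 and 1 adjusted over the list alone; list adjusted p = 0.121), with COL5A1 at -0.70 (SE 0.0953) and COL6A1 at -0.70 (SE 0.104). Against LvNC in place of sgNC, chosen after seeing the data, COL5A1 (-0.22, adjusted p = 0.154) and COL6A1 (-0.09, 0.626) were not called. With overexpression 2 of the 10 were higher and 1 lower (2 and 1 adjusted over the list alone, list adjusted p = 0.533). Cholangiocyte genes were higher in 5 of 17 cases and lower in 2 in the libraries labelled sgSLC12A5 (5 and 2 adjusted over the list alone; list adjusted p = 0.227), with the secreted phosphoprotein gene SPP1 at 1.10 (SE 0.163) and KRT7 at -0.40 (SE 0.0881). Against LvNC SPP1 was again higher (0.54, adjusted p = 0.0486) and KRT7 was not called (0.04, 0.814). With overexpression 2 of the 17 were higher and 5 lower (2 and 7 adjusted over the list alone, list adjusted p = 0.243).

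The tests of SLC12A5 and of the short-transcript lists in pairs were chosen after the results were seen. The other tests of those lists were written before these, but they address a pattern found in these data. SLC12A5 was higher in the libraries labelled knockdown, with 66 counts against 20, a ratio of 3.36 (95% exact Poisson interval 2.01 to 5.86, counting error only). Counting noise alone does not account for it, since the exact two-sided Poisson p was 3.67e-07. If guide and control labels of that arm had been swapped and SLC12A5 acted by dose, same-direction calls would exceed opposite ones as labelled, but the ratio of opposite to same-direction calls was 10.1, and 6.55 after a correction for GC content and transcript length. That ratio does not decide, since control lines that differ could give opposite calls too, and the sgSLC12A5 libraries differed from LvNC in 1121 genes and the sgNC libraries in 4118, as a swap would also have it. A swap therefore stays open, as do an edited gene that gains transcript while losing protein and a column code read wrongly, which were not tested.

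Short-transcript lists (respiratory chain, ribosomal proteins, histones, mitochondrial DNA) were lower with overexpression at the preset correlation but not with an estimated one (adjusted p = 0.636, 0.66, 0.622 and 0.66), their median transcript lengths being 923.8, 817.5, 754 and 784 bases against 2089 over all tested genes. Without LvNC replicate 3, 3 of the 4 lists were still called, which argues against that library alone, and after a correction for GC content and transcript length 2 of the 4 were called. For the respiratory chain and the histones both lists, 2 of 2, were called at the preset correlation, with medians going from -0.142 (interquartile range 0.198) to -0.0951 (0.179) and from -0.725 (0.631) to -0.696 (0.597). For ribosomal proteins and mitochondrial DNA, 0 of 2 passed, the medians shrinking from -0.102 (0.155) to -0.0628 (0.175) and from -0.195 (0.117) to -0.110 (0.15), so for these a part from length or GC content may remain and stays open. A lower transcript level of these genes with overexpression stays open too, as do the losses without LvNC replicate 2, where 0 lists were called.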
